A study of Rattus norvegicus with 2 samples.

How the data were processed

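Spatial RNA profiles were measured on 2 tissue sections from uninjured patellar tendons of male wild-type Sprague-Dawley rats, 1 section per tendon. Per the labels' protocols, frozen sections were fixed in methanol and permeabilised, and polyA RNA libraries were made with a 10x Visium kit, which captures RNA on a grid of barcoded spots and marks each captured molecule with a unique molecular identifier (UMI). A spot covers a small area that can hold several cells or parts of cells. The labels put both sections in 1 group and number them 1 and 2, and do not say whether both tendons came from the same rat. P-values of the comparisons between parts therefore cover only the spread between these sections, together with the spread shared across genes.

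The deposited count matrices hold UMI counts per gene and spot under tissue, not normalised. Per the submitters' processing notes, the build was Rnor_6.0 and the tools included Space Ranger 1.31 and Seurat, with no role given for either. The deposited spatial tables hold for each gene Moran's I, a score of how alike neighbouring spots are, and its p-value and adjusted p-value as the authors' software gave them. That p-value asks whether a gene's spots are arranged at random within a section, not whether tendons differ. The transform behind that score is not given in the sources used here. The same deposited tables give UMI counts per gene, which equalled the sums of the matrices, and a mean signal of counts scaled to the median spot total. Grid positions were taken from the deposited position lists. Image files were not analysed here.

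Sections 1 and 2 held 2179 and 1624 spots under tissue, with 3197050 and 3384765 UMIs. The median spot held 1130 and 1605.5 UMIs. Spots under 200 UMIs were left out of the comparisons (26 and 6 spots), except for Moran's I, which used all spots under tissue. UMIs were summed per section and part. Spots were not treated as replicates in the comparisons of sums. The p-values of Moran's I and the intervals of region shares do take spots as units.

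Parts were set in 3 ways. Depth was the number of grid steps to the nearest position off the tissue, with off-tissue patches of fewer than 10 positions counted as tissue: border was depth 1 to 2, intermediate 3 to 4 and core 5 or more. Ends were the outermost 25% of the long axis at each side and middle the rest. Regions were Leiden clusters of spots (resolution 0.5, 15 neighbours, 20 components) from log counts scaled to 10000 per spot, over 2000 variable genes scaled within each section. Genes of the fixed lists and mitochondrial and ribosomal protein genes were kept out of the clustering, and genes that built the regions were left out of the calls between regions. Regions with at least 20 spots in both sections were compared, which left 3 of 4. Scanpy 1.11.5 was used with Python 3.11.15.

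Sums were compared with edgeR 4.0.16 (quasi-likelihood test, TMM normalisation, its default filter on low counts) in R 4.3.3, with the section as a block, because parts of a section come from the same tissue. Adjusted p-values are Benjamini-Hochberg values and the threshold was 0.05. The fits had 2 residual degrees of freedom for depth bands and regions and 1 for ends against middle, so the calls lean on the spread shared across genes. Errors of folds are standard errors derived from the fold and its F statistic. In each section alone the log2 ratio of CPM (prior count 2) was taken. CPM in the comparisons of sums use totals scaled by TMM. CPM of single ends and of region 4 use plain totals, so these values are not on the same scale. A total of 30 gene lists were fixed before the data were examined, and 331 of their genes were matched to the annotation by symbol or older symbol, through a GRCr8 gene table used for names only. Among the 11 genes not matched was Col1a2, so the tendon fibroblast and fibrillar collagen lists were tested without it. Lists with at least 3 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry.

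Named genes followed a rule fixed before the data were examined. Spatial genes were the 20 with the highest mean Moran's I among those past the threshold in both sections and detected in at least 10% of the spots of both. For each contrast they were up to 12 genes per direction with the largest fold among those past the threshold, with the same sign in both sections and a mean of at least 50 CPM. For each list they were up to 4 members past the threshold, and regions were named by the 8 clustering genes with the largest fold. Genes named outside this rule are said to be so.

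The fits were tested on simulated counts with 200 changed genes. For border against core (8110 genes), 57% of genes changed 2-fold and 95% of those changed 4-fold were recovered, and 11.6% of calls were false. For ends against middle (8769 genes) these shares were 37%, 91% and 5.19%, and for region 1 against the others (7935 genes) 60%, 94% and 13.5%. The share of false calls thus lay above the nominal 5% in these simulations. It depends on how many genes change, so these shares do not carry over to the calls in the data. In the same simulations a list of 12 genes raised 2-fold was called by camera at the preset correlation and was missed with an estimated correlation and by fry in all 3 comparisons. With an estimated correlation camera rests on the residual degrees of freedom, 2 or 1 here. A list that does not pass there is therefore neither backed nor weakened by it. None of 30 unchanged lists was called by any of them. The simulated genes were drawn independently, so these runs cannot show how often lists of genes that vary together are falsely called. For border against core the correlations estimated in the data ran from -0.041 (matrix proteases) to 0.987 (skeletal muscle markers).

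Moran's I was also recomputed over adjacent spots. A first version, with counts scaled to 10000 per spot, failed on simulated counts: 321 and 199 of 800 unchanged genes were called in sections 1 and 2. Scaling to the median spot total gave 28 and 12 false calls, and Pearson residuals gave 1 and 0, so these replaced it. They recovered few of the changed genes, 4% to 13% at the median scale and 2% to 9% with Pearson residuals, against 23% to 37% at the scale of 10000, so the recomputed score misses most such changes. At the median scale the 28 false calls of section 1 stood against 6 and 13 recovered genes (2-fold and 4-fold). In section 2 the 12 stood against 4 and 9, so a large share of calls at that scale was false. The regions had been built at the scale of 10000 before this was seen; they were kept, and regions at the median scale were added as an alternative. Other alternatives were DESeq2 1.42.0 (size factors, and its Wald test), no filter on low counts, no block, at least 500 UMIs per spot, thinned sums, other bounds of bands and ends, other resolutions, and each section alone. Alternatives chosen after seeing the data were leaving out region 1 spots, regions from spots thinned to 500 UMIs, regions at the median scale, and Pearson residuals.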

Results

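Gene expression was mapped over sections of 2 uninjured rat patellar tendons, the band of dense connective tissue that joins the kneecap to the shin bone. Section 1 held 2179 spots under tissue with 3197050 UMIs and section 2 held 1624 spots with 3384765 UMIs. The median spot held 1130 UMIs and 582 genes in section 1, and 1605.5 UMIs and 715.5 genes in section 2. At least 1 UMI was found for 13416 and 14051 of the 25399 annotated genes. The study has a single group, so the comparisons below are between parts of the same sections. The sections were the replicates in the comparisons of sums (n = 2), and the summed libraries held 352493 to 2489518 UMIs.

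The first question was which transcripts are arranged in space. Genes of the tendon matrix were among those with the highest Moran's I in the authors' deposited tables. Col1a1, the main chain of tendon collagen, had values of 0.715 and 0.779 in sections 1 and 2 in the authors' deposited tables, Comp, a matrix protein that binds collagen, 0.578 and 0.724, Chad 0.534 and 0.758, Cilp2 0.589 and 0.602, and the small proteoglycans Dcn and Fmod 0.559 and 0.727 and 0.527 and 0.602. A second set was made of genes of fat tissue, with Cfd at 0.507 and 0.660, Fabp4 at 0.404 and 0.621 and Ca3 at 0.419 and 0.556 in the authors' deposited tables. The haemoglobin gene Hba-a1 had 0.502 and 0.616, and Apoe, a lipid carrier, 0.455 and 0.658, in the same deposited tables. The highest mean belonged to the clone-named gene AABR07000398.1, with 0.887 and 0.634 in the authors' deposited tables. Sparc, Cst3, Clu, Ecrg4, Spp1, Hba-a2, Sncg and NEWGENE_621351 (ENSRNOG00000011292) completed the 20 genes named by the rule.

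By the authors' deposited scores, 1762 genes passed an adjusted p of 0.05 in section 1 and 2414 in section 2, and 1014 passed in both. Independent lists of these sizes among the 12793 genes seen in both sections would share 332. Among the 1575 genes detected in at least 10% of the spots of both sections, 644 passed in both, against 457 for independent lists. Across those 1575 genes the deposited scores of the sections correlated with r = 0.838 (Spearman 0.678), a description across genes, which are not independent replicates. Of the fixed lists, 11 of 13 adipocyte markers passed in both sections (12 adjusted over the list alone), 11 of 12 macrophage markers (11 over the list alone), 10 of 11 endothelial markers (10), 8 of 11 tendon fibroblast markers (9) and 8 of 10 small leucine-rich proteoglycan genes (8). For skeletal muscle markers 3 of 12 passed in section 1 and 11 in section 2, and for neutrophil and marrow myeloid markers 4 and 7 of 8. Whether the sections differed was not tested. Of the other lists, 10 of 13 mitochondrially encoded genes passed in both sections (11 over the list alone), 7 of 13 cartilage and fibrocartilage markers (7), 2 of 7 bone and osteoblast markers (3), 1 of 3 osteoclast markers (1), 1 of 9 proliferation genes (1) and 0 of 5 lymphocyte markers (0). UMIs per spot were themselves arranged in space (recomputed Moran's I of 0.862 and 0.819 for log UMIs), and 671 genes passed in both sections when the score was recomputed from log counts scaled to the median, of which 664 were among the 1014. In simulated counts a large share of the calls at this scale within a section was false. Pearson residuals gave fewer false calls there but missed most changes. With them 742 genes passed in both sections, of which 703 were among the 1014.

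The border of the sections was next compared with their core. Fat genes were among the largest rises. Cfd, which encodes the adipokine adipsin, averaged 5918 CPM in the border and 862 CPM in the core, a log2 fold of 2.83 ± 0.21 (SE, 2 sections). Retn, which encodes resistin, rose by 2.90 ± 0.21 and the lipid-droplet gene Cidec by 2.68 ± 0.23. Lipe, the hormone-sensitive lipase, rose by 2.65 ± 0.21 and Clec3b by 3.26 ± 0.30. The named genes that fell included matrix genes of the tendon. Scx, a transcription factor of tendon cells, had a log2 fold of -2.23 ± 0.20, Prg4, which encodes the lubricant lubricin, -2.39 ± 0.18, Cilp2 -2.37 ± 0.22 and Chad -2.30 ± 0.21.

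Among the other genes named by the rule, S100a8 and S100a9, abundant proteins of neutrophils, rose by 2.66 ± 0.20 and 2.83 ± 0.40. Ca3, Gpd1, Thrsp, Agt and AABR07005821.1 rose by 2.64 to 2.76. Serpina1 had a log2 fold of -2.84 ± 0.24 and Itga10, a collagen receptor subunit, -2.80 ± 0.26, followed by Fibin at -2.45, Ndufa4l2 at -2.35, Calhm5 and Ucma at -2.24, Adamtsl2 at -2.19 and AABR07054614.1 at -2.17.

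**Figure D1:**
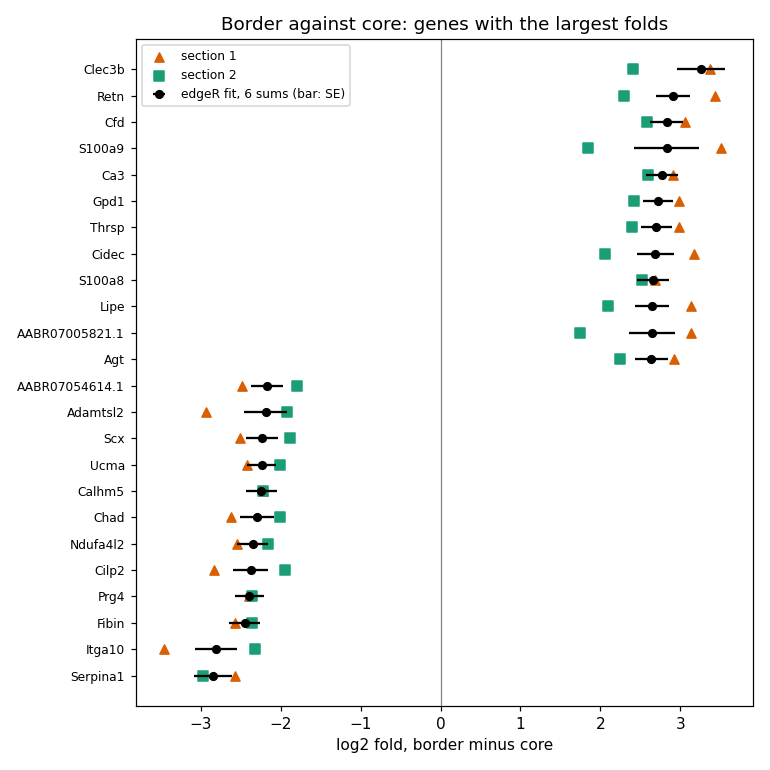
Log2 fold of border minus core (x axis) for the 24 named genes, with the edgeR estimate and its standard error in black and each section's own log2 ratio as a triangle or square. The estimates run from 3.26 for Clec3b to -2.84 for Serpina1, and the naming rule kept genes with the same sign in both sections.

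The fixed lists divided by tissue. All 12 tested adipocyte markers rose (12 adjusted over the list alone), with a median log2 fold of 2.59. All 11 endothelial markers rose (11), among them Egfl7 by 2.04 ± 0.22 and Tek by 1.80 ± 0.24, and all 12 macrophage markers (12), among them Cd74 by 1.76 ± 0.21 and C1qa by 1.67 ± 0.18. All 5 mast cell markers rose (5), 7 of 8 neutrophil and marrow myeloid markers (7), 10 of 11 skeletal muscle markers (11), including Mylpf by 2.99 ± 0.30, 6 of 9 mural cell markers (6) and 6 of 11 loose connective tissue fibroblast markers (7), of which 1 fell. The rise of skeletal muscle markers may rest mainly on section 2. Section 1 held 75 and 31 of their UMIs at its ends and 298 in its middle, against 832, 71 and 2350 in section 2. The neutrophil markers Defa5, Np4 and RatNP-3b also lay mainly in section 2. They held 10, 11 and 23 UMIs in section 1 and 2282, 2312 and 2656 in section 2 in the authors' deposited tables. S100a8 and S100a9 rose in both sections. Of the tendon fibroblast markers 7 of 9 fell (7) and 1 rose, with Fmod at -2.12 ± 0.21, Comp at -2.03 ± 0.21 and Col1a1 at 39093 CPM in the border and 154888 CPM in the core. Small leucine-rich proteoglycan genes fell in 8 of 9 cases (8), including Dcn at -1.91 ± 0.22, and cartilage and fibrocartilage markers in 5 of 8 (6), including Acan at -2.10 ± 0.27 and Clec3a at -2.03 ± 0.20. Collagen modification and crosslinking genes fell in 9 of 14 cases (10), with 2 that rose, including Plod2 at -2.16 ± 0.19 and Lox at -1.73 ± 0.19. Every list in this paragraph passed camera at the preset correlation, and none did with an estimated correlation (adjusted p of 0.227 or higher) or by fry (adjusted p of 0.0512 or higher).

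Bone and osteoblast markers fell in 6 of 7 cases (7 over the list alone), fibrillar collagens in 4 of 8 (5) with 2 that rose, fibril-associated collagens in 6 of 9 (6) with 1 that rose, YAP target genes in 4 of 7 (5), mitochondrially encoded genes in 8 of 13 (9) with 1 that rose, and synovial lining markers in 2 of 7 (2). Nuclear-encoded oxidative phosphorylation genes rose in 5 of 14 cases (8) and Schwann cell markers in 3 of 6 (3) with 1 that fell. These lists passed camera at the preset correlation as well, with an adjusted p of 0.227 or higher with an estimated correlation. For synovial lining markers camera's direction and the mean (-0.30) were negative and the median (0.03) was positive. The fall of bone markers may rest on section 2 for some members. In the authors' deposited tables Bglap held 4 UMIs in section 1 and 5229 in section 2, while Spp1 held 2361 and 963. Erythroid, protease, elastic fibre, immediate-early, heat-shock, hypoxia and TGF-beta family lists did not pass camera. Osteoclast, lymphocyte and proliferation lists had fewer than 3 tested members.

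**Figure D2:**
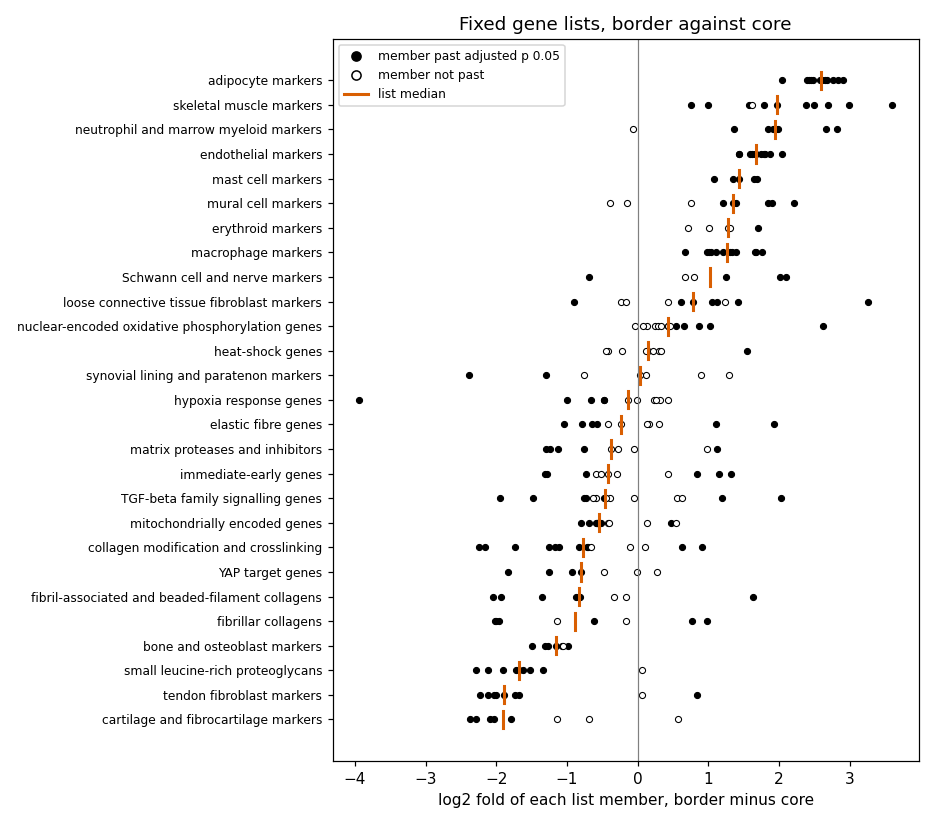
Log2 fold of border minus core (x axis) for each tested member of the fixed gene lists (rows), filled where the member passed an adjusted p of 0.05 and open where it did not, with the list median as a bar. Adipocyte markers have the highest median (2.59) and cartilage and fibrocartilage markers the lowest (-1.91).

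In all, 1131 of 8110 genes were higher in the border and 924 lower by edgeR's quasi-likelihood test, and 1127 and 920 of these had the same direction in both sections. The calls came from these same sections, so that agreement is largely built in. Of all tested genes, 71.7% had the same direction in both sections. The ratios of the sections correlated with r = 0.698 across tested genes. In simulated counts with this design 11.6% of calls were false, above the nominal level. Spots of region 1, described next, made up 41.1% and 57.3% of the border spots and 11.6% and 15.6% of the core spots of sections 1 and 2, and without them 102 genes were higher and 41 lower among 2509 tested. Without the block the counts were 522 and 347, and the DESeq2 Wald test gave 475 and 341.

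Clustering of the spots gave 4 regions, of which 3 had enough spots in both sections. Region 1 was led among the clustering genes by Gpd1, Thrsp, Sncg, Nnat, Ces1d, Cdo1, Apoe and Fasn and held 20.6% of the spots of section 1 (95% exact binomial interval 18.9 to 22.4) and 31.1% of section 2 (28.9 to 33.5). Region 2 was led by Thbs1, AABR07000398.1, Angptl7, Abi3bp, AABR07015057.1, Aff2, AC134224.2 and AC134224.1 and held 41.0% (38.9 to 43.1) and 38.6% (36.2 to 41.1). Region 3 was led by Scrg1, Serpina1, Ndufa4l2, Pla2g2a, Adamtsl2, Tnfrsf11b, Mt2A and Clu and held 35.7% (33.6 to 37.7) in section 1 and 485 of 1618 spots in section 2. The intervals cover counting error only and take spots as independent, which neighbouring spots are not. In region 3, 94.0% and 84.1% of the spots lay in the core. The median spot of region 2 held 493 and 864 UMIs, against 2107 and 1812 in region 3 and 1546 and 2963 in region 1. Clustering again with 10 other random seeds gave an adjusted Rand index against these regions of 0.384 to 0.841, so the boundaries moved with the seed. The index was 0.319 with counts scaled to the median and 0.419 with spots thinned to 500 UMIs.

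**Figure D3:**
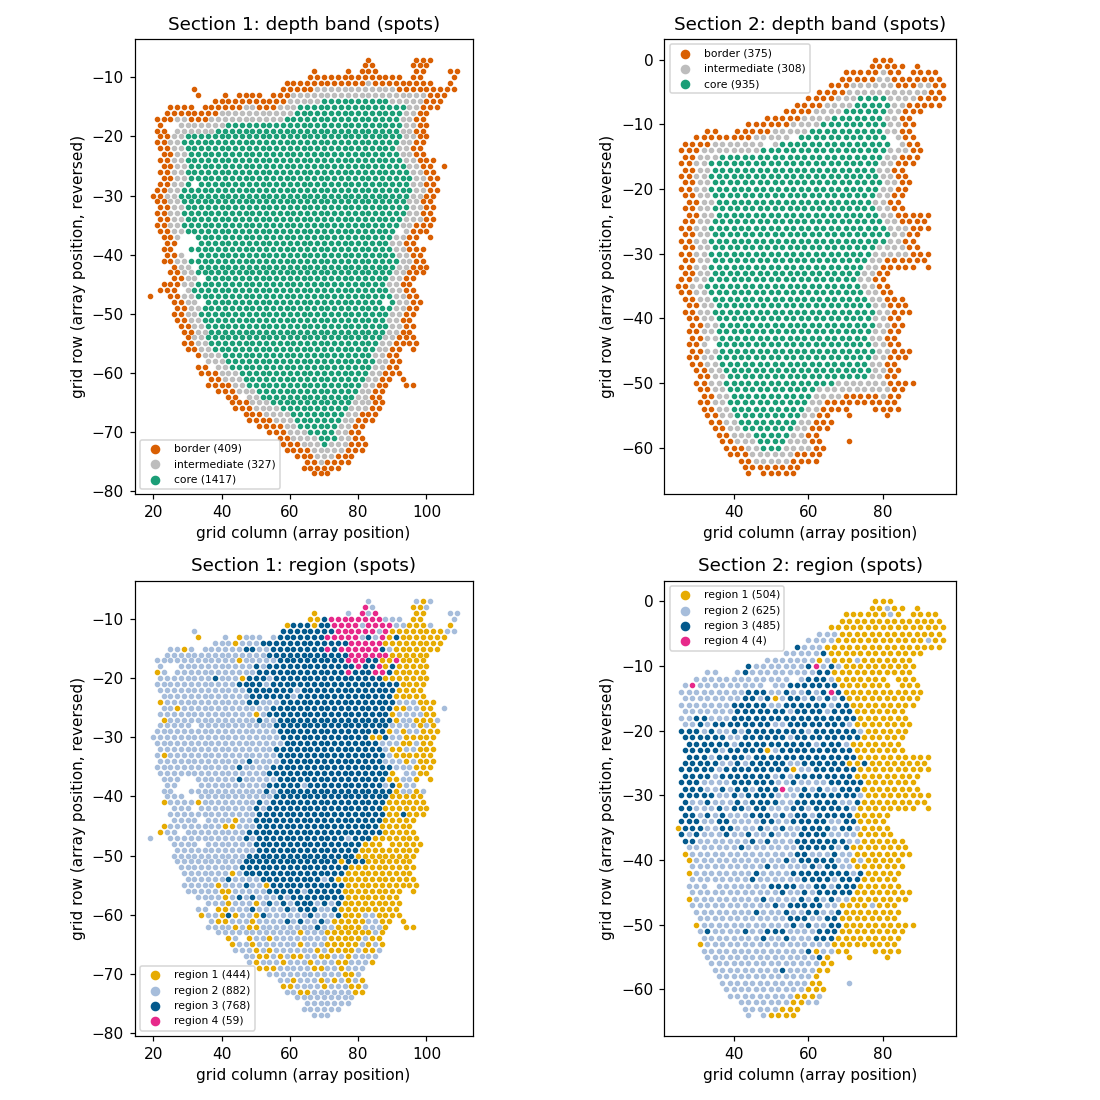
Spots of both sections at their grid positions (axes, array rows and columns), coloured by depth band in the upper panels and by region in the lower panels, with the number of spots in brackets. Region 1 runs along the right edge of both sections as drawn (444 and 504 spots), and region 4 is a patch of section 1 (59 spots).

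Among genes that had not built the regions, region 1 was set apart from the mean of the other regions by vessel, immune and fat genes. The regions were drawn from the same spots' counts, so genes that vary with the clustering genes differ between regions partly by construction. Calls and p-values between regions therefore describe the regions and do not test whether they exist. All 12 adipocyte markers, 11 endothelial markers, 12 macrophage markers, 5 mast cell markers and 4 erythroid markers tested were higher in region 1, with the same counts adjusted over the list alone. Lipe rose by 3.26 ± 0.23, Agt by 3.34 ± 0.23, Fcna by 3.11 ± 0.22 and Des, a muscle and mural cell filament gene, by 2.81 ± 0.24. Vwf, the clotting factor carrier made by endothelium, rose by 2.40 ± 0.21. Clec3a had a log2 fold of -3.39 ± 0.21, Prg4 -3.13 ± 0.53, Itga10 -2.84 ± 0.26 and Comp -2.27 ± 0.25. Col2a1, the main cartilage collagen, had -3.04 ± 0.72, with -0.26 in section 1 and -3.70 in section 2. Retn, Scd, Cfd, Sort1, Trarg1, S100a9, Ca3 and Cidec rose by 2.85 to 3.11, and Chad, Fibin, Cox4i2, Pla2g5, Plod2 and Ecrg4 fell by 2.31 to 2.79. Small leucine-rich proteoglycan genes fell in 8 of 9 cases (8 over the list alone), with 1 that rose. By edgeR, 980 of 6367 genes were higher and 664 lower, and r between the sections' ratios was 0.766 across genes. The DESeq2 Wald test gave 477 and 274. Of the other lists, mural cell markers were higher in 7 of 9 cases (7), neutrophil and marrow myeloid markers in 6 of 7 (7), loose connective tissue fibroblast markers in 7 of 11 (9) with 1 lower, skeletal muscle markers in 5 of 8 (5) and Schwann cell markers in 4 of 6 (4) with 1 lower. Cartilage and fibrocartilage markers were lower in 6 of 8 cases (7), tendon fibroblast markers in 7 of 10 (7) with 1 higher, collagen modification genes in 9 of 14 (10) with 2 higher, mitochondrially encoded genes in 9 of 13 (10), fibril-associated collagens in 5 of 9 (5) and fibrillar collagens in 4 of 8 (5) with 2 higher in each, bone markers in 3 of 7 (3) with 1 higher and YAP target genes in 3 of 7 (4). These lists passed camera at the preset correlation, no list passed with an estimated correlation (adjusted p of 0.314 or higher), while by fry collagen modification genes (adjusted p = 0.0239) and mitochondrially encoded genes (adjusted p = 0.00162) did.

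Region 3 had the reverse arrangement on many of these lists. Cilp2 averaged 12739 CPM there and 4327 CPM elsewhere (log2 fold 1.82 ± 0.21), and Comp rose by 1.65 ± 0.21, Acan, the main cartilage proteoglycan, by 1.71 ± 0.20, Itga10 by 2.02 ± 0.21 and Prg4 from 292 to 817 CPM. Of the tendon fibroblast markers 6 of 10 were higher (6 over the list alone) and of the small leucine-rich proteoglycan genes 6 of 9 (7). Adipocyte markers were lower in 11 of 12 cases (12) and endothelial markers in 11 of 11 (11), with Lipe at -3.06 ± 0.33 and Adipoq at -2.97 ± 0.29. Cartilage and fibrocartilage markers were higher in 4 of 8 cases (5), collagen modification genes in 8 of 14 (8) with 1 lower and immediate-early genes in 4 of 11 (4). Lower were 9 of 12 macrophage markers (10), 7 of 11 loose connective tissue fibroblast markers (8), 6 of 9 mural cell markers (6), 6 of 7 neutrophil and marrow myeloid markers (7), 4 of 5 mast cell markers (5), 4 of 4 erythroid markers (4), 3 of 6 Schwann cell markers (4) and 2 of 8 skeletal muscle markers (2). In all 408 genes were higher and 559 lower by edgeR, against 122 and 203 with the DESeq2 Wald test, and the balance turned to 357 and 284 with regions at the median scale and to 204 and 101 at resolution 0.8. These lists passed camera at the preset correlation but not with an estimated correlation (adjusted p of 0.319 or higher). The contrasts of the regions share the same sums, so their opposite signs are partly built in.

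Few genes separated region 2 from the mean of the others once the genes that built it were set aside. That mean joins regions 1 and 3, which had opposite signs on many lists (adipocyte medians of 2.83 and -2.93). A region lying between them would give few calls. Matrix lists higher in region 2 may also reflect low values in region 1 alone. Region 2 was not tested against region 3 alone. By edgeR 7 genes were higher and 0 lower. At an unadjusted p under 0.05 there were 641 genes, and the DESeq2 Wald test gave 2 higher and 0 lower. Without the block, and against the sum of all other spots, 0 were higher and 0 lower. The 7 were P4ha1, an enzyme of collagen hydroxylation (1.89 ± 0.30), Clec3a (1.63 ± 0.18), Itgbl1 (0.97 ± 0.18), Tmem47 (0.89 ± 0.16) and the mitochondrially encoded Mt-atp8 (1.44 ± 0.18), Mt-nd4l (1.39 ± 0.21) and Mt-nd5 (0.84 ± 0.16). The ratios of the sections correlated with r = 0.0934 across genes. Mitochondrially encoded genes rose in 3 of 13 cases (6 over the list alone, median 0.44), a list that camera placed higher at the preset correlation and not with an estimated correlation (adjusted p = 0.388), and that passed by fry (adjusted p = 0.00374). Matrix lists had larger medians and were also placed higher by camera at the preset correlation: cartilage and fibrocartilage markers (median 1.01, 1 of 8 members past the threshold, 2 over the list alone), bone markers (0.85, 0 of 7, 4), fibrillar collagens (0.71, 0 of 8, 3), tendon fibroblast markers (0.56, 0 of 10, 6) and small leucine-rich proteoglycan genes (0.47, 0 of 9, 2). So were TGF-beta family signalling genes (0.38, 0 of 14, 2), which passed by fry as well (adjusted p = 0.0462), matrix proteases (0.39, 0 of 9, 1), YAP target genes (0.37, 0 of 7, 1), fibril-associated collagens (0.18, 0 of 9, 2) and collagen modification genes (0.15, 1 of 14, 5). Nuclear-encoded oxidative phosphorylation genes were placed lower (-0.23, 0 of 13, 0). None of these lists passed with an estimated correlation (adjusted p of 0.388 or higher). With regions built from spots thinned to 500 UMIs, Mt-atp8 and Mt-nd4l turned to -0.41 and -0.0462, and with regions built at the median scale Clec3a turned to -0.28.

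The ends of the long axis were last compared with the middle. Defa5, a defensin of neutrophils, had the largest fold, 5.35 ± 0.27, which rested on section 2, since section 1 held 8 UMIs in its ends and 2 in its middle. Mast cell gene Mcpt1l1 rose by 0.85 ± 0.15, Serpine2 by 0.88 ± 0.15, Cxcl14 by 0.76 ± 0.13, Sfrp2 by 0.65 ± 0.14 and Mt-nd4l by 0.90 ± 0.18. Matrix genes were among those that fell, with Matn4 at -1.10 ± 0.20, Cilp2 at -0.75 ± 0.14, Col11a2 at -0.73 ± 0.14 and Mfap4, of elastic fibres, at -0.82 ± 0.17. Adamtsl2, Serpina1, Abca2, Ssc5d, C1qtnf6, Olfml3, Cytl1 and NEWGENE_621351 (ENSRNOG00000011292) fell by 0.59 to 0.98.

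Bone and osteoblast markers had a median log2 fold of 1.79 between ends and middle, with Mepe and Dmp1, both genes of bone cells, higher by 2.80 ± 0.28 and 2.14 ± 0.38 (2 of 7 members, 3 adjusted over the list alone). Both rest on section 2: their ratios in section 1 were 0.00 and -0.91. In section 1 Ibsp and Spp1 had the highest ratios of the list, 3.37 and 2.45, and neither passed. Camera at the preset correlation placed this list higher (adjusted p = 1.46e-10). With an estimated correlation its adjusted p was 0.899, in a test that could hardly pass with 1 residual degree of freedom. Most of the list's CPM lay at a single end of each section. In section 2 it was 10315 at that end, 617 in the middle and 204 at the other end, and in section 1 it was 2109, 306 and 139. Bglap, the osteocalcin gene, accounted for 4557 of the UMIs at that end of section 2, and section 1 held 1 Bglap UMI at the corresponding end, where Spp1 gave 1785.

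Of the Schwann cell and nerve markers 2 of 7 rose (2 adjusted over the list alone), including Mbp, of myelin, by 1.91 ± 0.30, 2 of 5 mast cell markers rose (3), and the neutrophil and marrow myeloid list had a median of 4.09 with 1 of 6 members past the threshold (1). The neutrophil and marrow myeloid list was high at 1 end of section 2 alone, with 15374 CPM against 238 in the middle and 233 at the other end, while in section 1 the ends stood at 163 and 203 CPM and the middle at 252. Camera placed the Schwann cell, mast cell and neutrophil lists higher at the preset correlation, and with an estimated correlation each had an adjusted p of 0.899. Camera also placed erythroid markers (0 of 6 members past the threshold, 3 over the list alone) and hypoxia response genes (0 of 11, 0 over the list alone) higher. It placed tendon fibroblast markers (0 of 10, 1 over the list alone), fibril-associated collagens (0 of 9, 4), small leucine-rich proteoglycan genes (0 of 9, 4 lower and 1 higher) and elastic fibre genes (1 of 11, 2) lower. None of these lists passed with an estimated correlation (adjusted p of 0.899 or higher). Hypoxia response genes stood at 2181 and 982 CPM at the ends of section 1 against 1300 in the middle. In section 2 they stood at 1193 and 888 against 1121, so the rise was not shared by all ends. Erythroid markers stood at 4443 and 10540 CPM against 5410 in section 1, and at 14294 and 8121 against 3987 in section 2. For Schwann cell markers these values were 803 and 982 against 793, and 1092 and 939 against 853.

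By edgeR 16 of 8769 genes were higher at the ends and 14 lower, with 1 residual degree of freedom. The DESeq2 Wald test and the fit without the block gave 0 in both directions, the unadjusted p lay under 0.05 for 839 genes, and the ratios of the sections correlated with r = 0.116 across genes. These calls therefore depend on the model used.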

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

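These values were chosen after the data were seen. Region 4 was left out of the comparisons between regions, because section 2 held only 4 of its spots against 59 in section 1, while its spots stayed in the sums of depth bands and ends. In those spots of section 1, Chi3l1, a secreted glycoprotein gene, stood at 19919 CPM (1696 UMIs) against 711 CPM in the other spots. Lbp, which encodes a lipopolysaccharide binding protein, stood at 5790 CPM (493 UMIs) against 196, and the metallothionein gene Mt1 at 1891 CPM (161 UMIs) against 120. Spp1 stood at 7423 CPM (632 UMIs) against 556. All 59 spots lay at the end of section 1 where the bone and osteoblast list was high, and 1785 of the 1852 UMIs of that list there were Spp1, so the patch and the bone list overlap. The difference between the sections was not tested, and no explanation was tested.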

How the results depend on the processing

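Leaving out region 1 spots, regions from spots thinned to 500 UMIs, regions at the median scale and Pearson residuals were chosen after the data were seen. Where no cause is given, the cause was not tested. The number of genes with spatial arrangement in both sections (1014) was 170 with Moran's I of at least 0.1 as well, 644 among genes detected in 10% of spots (fewer genes tested), 671 with the score recomputed and 443 recomputed without border spots, and one section alone gave 1762 to 2414. Scaling to 10000, which failed on simulated counts, gave 1480, and Pearson residuals gave 742. Border against core (1131 higher, 924 lower) gave 475 and 341 with the DESeq2 Wald test, 522 and 347 with no replicate block, 500 and 431 with thinned sums (fewer genes tested), and 102 and 41 without region 1 spots (2509 genes tested). Ends against middle (16 and 14) gave 0 and 0 with DESeq2 and 0 and 0 with no replicate block, 48 and 47 with no filter, 45 and 30 with thinned sums, 3 and 1 with at least 500 UMIs per spot, 10 and 8 with longer ends, 38 and 30 without border spots, and 6 and 0 without region 1 spots.

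Region 1 (980 and 664) gave 477 and 274 with DESeq2, 632 and 442 with thinned sums, and 369 lower with no replicate block. Region 2 (7 and 0) gave 2 higher with DESeq2, 38 and 19 with no filter, 0 higher with no replicate block, 28 and 1 with at least 500 UMIs, 22 higher at resolution 0.3, and 0 higher against the sum of all other spots. Region 3 (408 and 559) gave 122 and 203 with DESeq2, 136 and 205 with no replicate block, 208 and 264 with thinned sums, 204 and 101 at resolution 0.8 (the share of higher calls rose from 42.2% to 66.9%), and 825 and 1081 against the sum of all other spots. With regions from thinned spots, regions 2 and 3 were matched to the same region, so both gave 928 and 1295, and in region 2 Mt-atp8 turned to -0.41 and Mt-nd4l to -0.0462. At the median scale region 2 gave 150 and 14, with Clec3a at -0.28, and region 3 gave 357 higher and 284 lower (55.7% higher, against 42.2%); only 45.8% of region 2 spots fell in its matched region, so these are not the same spots.

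With an estimated correlation, which also missed the changed list in simulated counts, 0 lists passed in each of the 5 contrasts. By fry 0 passed for border against core, ends against middle and region 3, and 2 each for region 1 and region 2. Named genes kept their direction in all other cases: 223 of 236 values for border against core stayed past the threshold, 80 of 162 for ends against middle, 257 of 264 for region 1, 43 of 77 for region 2 and 249 of 264 for region 3. All 60 values of the 20 spatial genes in the recomputed scores did so. Values of 1 section alone are not counted, since the naming rule fixed their direction and leaving out a section leaves no residual degrees of freedom. Low counts limit the calls: in simulated border against core sums, 34.7% of 2-fold changes were recovered for genes under 234 UMIs and 78.4% for the others, a split chosen after the data were seen.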

Other observations

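Of the tests in this part, the one that left out AABR07000398.1 was written before its result was seen, and the others were chosen after the results were seen.

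Several genes had a spatial pattern in one section that was near 0 in the other, and these were picked by the size of that difference. In the authors' deposited tables Moran's I of Chi3l1 was 0.821 in section 1 with an adjusted p of 0.285 in section 2, and that of Lbp was 0.684 with an adjusted p of 0.808. Of genes arranged in section 2, Bglap, Defa5, Np4, Mpo and Ighm held 4, 10, 11, 45 and 22 UMIs in the whole of section 1 in the authors' deposited tables. At the end of section 2 that held the bone genes, Np4 stood at 4212 CPM, Mpo at 721 CPM and Ighm, an antibody heavy chain gene, at 872 CPM, against 49.4, 27.3 and 58.6 CPM in the middle.

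Cartilage and fibrocartilage markers were lower in the border than in the core. The border had fewer UMIs per spot in section 1 (median 680 against 1528) but more in section 2 (2054 against 1537). The list's median log2 fold stayed at -2.20 or below with at least 500 UMIs per spot and with thinned sums. Neither setting can decide whether depth is the cause. Thinning a whole sum leaves its expected folds unchanged. The bound of 500 UMIs kept 503118 of 551961 border UMIs in section 1 and 1036192 of 1058143 in section 2. Without the spots of region 1 the median of the 6 members still tested was -0.21, so dilution by region 1 may account for much of the difference. That test leans toward this outcome, because region 1 was separated by expression and its spots were poor in matrix transcripts. A difference between superficial and deep tendon cells stays open, and no biological explanation was tested.

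Region 2 stood apart from region 3. With every spot thinned to 500 UMIs, 72.0% of the 957 region 2 spots that had so many UMIs (of 1507) fell in the region that held most of region 3. That region held 1959 of all 3197 thinned spots, so a large share was likely in any case. Thinning also removes counts that separate regions, so this cannot decide whether the split follows UMIs per spot. Leaving out the abundant AABR07000398.1 changed the median log2 fold of mitochondrial transcripts by 0.00082, but taking out a transcript that is higher in region 2 can only raise the others there, so this decides nothing. Whether fewer UMIs reflect the tissue or its permeabilisation stays open, and no biological explanation was tested.

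Camera placed bone and marrow lists higher at the ends at the preset correlation, where 2 of 7 and 1 of 6 members passed. With an estimated correlation each had an adjusted p of 0.899, in a test that could hardly pass with 1 residual degree of freedom. The bone list had a median log2 ratio of 0.015 in section 1 and 1.09 in section 2, so the sections may not hold the same tissues, although Ibsp and Spp1 had ratios of 3.37 and 2.45 in section 1. Bone at both ends is argued against in section 2, where the list at the lower end stood at 0.331 times the middle. Whether the cut plane or the tendon differed cannot be read from the labels, and no biological explanation was tested.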
